A study of Mus musculus with 12 samples.

How the data were processed

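Total RNA from the white part of the gastrocnemius, a calf muscle made mostly of fast fibres, was measured on 12 Affymetrix MOE430A arrays, a mouse expression array on which each probe set reads 1 stretch of transcript sequence. Per the labels, 6 arrays came from male mice lacking the gamma3 subunit of AMP-activated protein kinase (AMPK), encoded by Prkag3, and 6 from wild type littermates. All mice were labelled C57BL/6, generation F7, aged 14 weeks and fasted overnight, and the design text calls the 6 of each genotype biological replicates. The deposited values are intensities that the authors made with RMA, per the submitters' processing notes, and the version of RMA was not given in the sources used here. RMA corrects the background, makes the intensity distribution alike on all arrays and combines the probes of a probe set. The deposited intensities are on a linear scale, from 7.47 to 21828, and log2 was taken before any test. Because RMA sets all arrays to nearly the same distribution, a change shared by most transcripts cannot be seen in these values. RMA also pulls small differences of dim probe sets towards 0. Array medians lay between 132.5 and 139.8 intensity units, and array pairs correlated at 0.991 to 0.997 over all probe sets, with 0 identical pairs. The number of arrays, 6 per genotype, limits the precision.

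Of the 22690 probe sets, 64 array controls were left out and 22626 were tested. Gene names came from the platform annotation, in which 20380 probe sets name 1 gene, 691 several and 1555 none here. Only probe sets that name 1 gene were used for named results, and they covered 12393 genes. Prkag3, Prkaa1, Prkaa2 and Prkab2 were not analysed here. The reference gene table (assembly GRCm38.p6) was used to update gene symbols, for the order of genes, and for distances and windows in Mb. The sources used here name no genome build, and no coordinates of the assembly are given.

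The array records deposited with the values were read for batches. The arrays were washed in 3 runs of 4, each with 2 knockout and 2 wild type arrays, and were scanned on 2 days. The records also gave a cage letter (3 letters, each with equal numbers of both genotypes) and 1 of 4 fluidics modules. Modules 1 and 2 held 2 knockout arrays and 1 wild type array each, and modules 3 and 4 the reverse. All arrays came from 1 chip lot. The genotype note in the record matched the label on 12 of 12 arrays. The log2 ratio of 3' to 5' control probe sets of Actb and Gapdh, a sign of RNA quality, averaged -0.129 ± 0.082 (SD, n = 6) in knockout and -0.142 ± 0.0311 (SD, n = 6) in wild type (exact permutation test, two-sided p = 0.747).

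Knockout was compared with wild type on log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with genotype as the only term and Benjamini-Hochberg adjustment over all tested probe sets. The threshold was an adjusted p of 0.05. A gene counted as changed when any probe set naming it alone passed. The test was checked on simulated data with the spread of these arrays. In 10 simulations of 22626 probe sets with 200 changed, it recovered 44.8% of changes of 0.25 on the log2 scale, 93.7% of changes of 0.5 and 99.8% of changes of 1, and 5.37% of its calls were unchanged probe sets. With 200 changed probe sets, an adjusted p of 0.05 is easier to reach than where few change. Recovery in the real comparison, in which 3 probe sets passed, would therefore be lower than these shares.

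Before the data were examined, 27 lists holding 436 genes of muscle metabolism, fibre type, signalling and other cell types were fixed, together with the rule for naming genes and the alternatives. Of these genes, 393 were measured, 11 of them through an older symbol, each represented by its probe set with the highest mean. The 26 lists with at least 5 measured genes were tested with limma's camera, which compares a list with all other genes, at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. Camera with an estimated correlation and limma's fry were run beside it. In the simulations, which held no correlation between genes, a list of 20 genes shifted by 0.1 passed in 10 of 10 and 0 of 250 unchanged lists passed. The naming rule took the AMPK subunit genes, the 12 largest rises and 12 largest falls past the threshold (filled up to 5 per direction by smallest p where fewer passed), and for each list up to 4 members past 0.05 adjusted over the list alone, or else the 2 with the smallest p.

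The alternatives fixed beforehand were the replicate number as a block, centring each array on its median, a further quantile normalization, only probe sets above the median level, a trended and robust prior variance, array weights, the wash run as a block, the mean of a gene's probe sets, and leaving out each array in turn. Cage letter and fluidics module as blocks, each wash run on its own, the lists without genes near Prkag3 and the slow fibre level as a covariate were added after seeing the data. For the list levels, the difference between genotypes was also tested by exact permutation of the 12 arrays, in 924 arrangements, with a smallest possible p of 0.0022. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.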

Results

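The white portion of the gastrocnemius was profiled in 6 mice lacking AMPK gamma3, a regulatory subunit of the energy-sensing kinase AMPK that is found mainly in fast glycolytic muscle, and in 6 wild type littermates, all 14 weeks old and fasted overnight. The comparison asks which transcripts of fast muscle differ in the absence of this subunit. Values are authors' RMA intensities on the log2 scale, and each change is knockout minus wild type with its standard error from limma over 6 against 6 arrays. Prkag3 itself was not analysed here, so the labels could not be checked against the targeted transcript.

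The other AMPK subunit genes that were measured lay at nearly equal levels in both genotypes. Prkab1, which encodes the scaffold subunit beta1, differed by 0.016 ± 0.055 (SE), Prkag1, the widely expressed gamma subunit, by -0.017 ± 0.0576, and Prkag2, a gamma subunit mutated in an inherited heart disease, by -0.017 ± 0.0611 (limma, adjusted p = 0.985, 0.985 and 0.987). The 95% intervals of these differences ran from -0.10 to 0.13 for Prkab1, from -0.14 to 0.11 for Prkag1 and from -0.15 to 0.11 for Prkag2. A dimmer Prkab1 probe set gave -0.12 ± 0.0667 (adjusted p = 0.877).

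The knockout muscle differed from wild type in 3 genes past the threshold, and all 3 fell. Stk25, a serine/threonine kinase of the germinal centre kinase family, fell by 0.91 ± 0.103 on the log2 scale, or by 46.7%. Neu2, the cytosolic sialidase, fell by 0.50 ± 0.0574, or by 29.5%. Stk11ip, whose product binds the AMPK-activating kinase LKB1, fell by 0.37 ± 0.0552, or by 22.4%. For each of the 3, every knockout array lay below every wild type array.

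Stk25 had a mean log2 intensity of 8.16 ± 0.106 (SD, n = 6) in knockout and 9.07 ± 0.284 (SD, n = 6) in wild type, with a limma adjusted p of 0.00117. The corresponding levels of Neu2 were 6.88 ± 0.0794 and 7.38 ± 0.111 (limma, n = 6, adjusted p = 0.00117), and those of Stk11ip 6.88 ± 0.111 and 7.25 ± 0.0626 (limma, n = 6, adjusted p = 0.0322). Each was read by 1 probe set, so a lower transcript level cannot be told apart from a sequence difference under its probes. With the wash run as a block the adjusted p was 0.000377 for Stk25, 0.00362 for Neu2 and 0.0365 for Stk11ip. In wash runs 1, 2 and 3 taken alone, the difference was -0.77, -0.78 and -1.18 for Stk25, -0.39, -0.52 and -0.60 for Neu2, and -0.33, -0.32 and -0.45 for Stk11ip. Stk25 and Neu2 passed in all 12 fits that left out 1 array, whereas Stk11ip passed in 2 of them, those without knockout replicate 4 and without wild type replicate 1, and its adjusted p ranged from 0.00438 to 0.127. Stk11ip did not pass either after centring each array on its median (adjusted p = 0.0611) or a further quantile normalization (adjusted p = 0.0528). It was also lost with the replicate number as a block (adjusted p = 0.115) and, added after seeing the data, with the fluidics module as a block (adjusted p = 0.242).

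**Figure D1:**
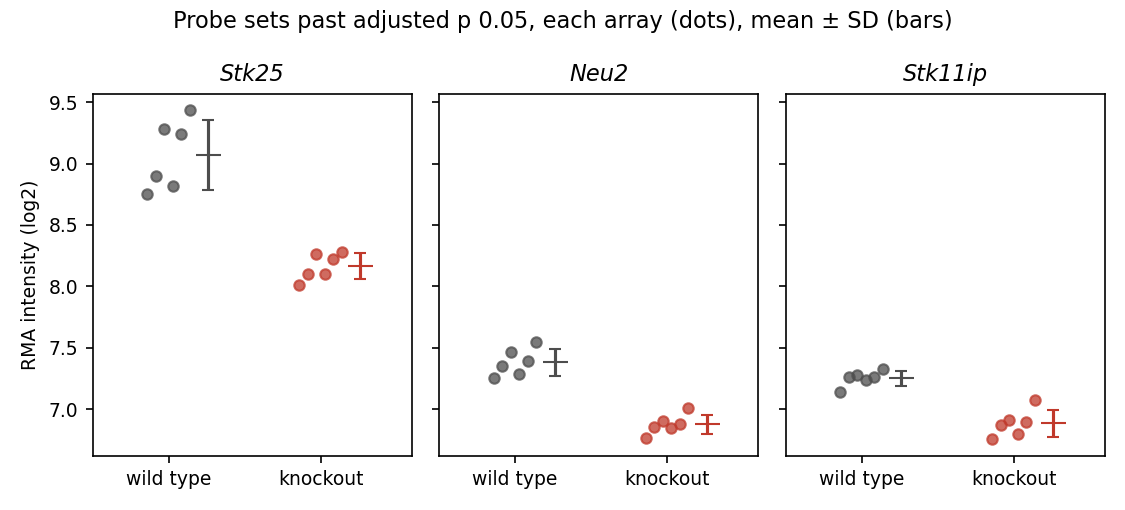
Log2 RMA intensity (vertical axis) of Stk25, Neu2 and Stk11ip in wild type and knockout muscle; each dot is 1 of 6 arrays per genotype and the bars give the mean ± SD. The knockout arrays lie below all wild type arrays for each gene, and the distance between the means is 0.91 for Stk25, 0.50 for Neu2 and 0.37 for Stk11ip.

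No gene rose past the threshold. The 5 rises with the smallest p, none of which passed, were Tmcc2 (0.27 ± 0.0467, adjusted p = 0.123), Rpl22, a protein of the large ribosomal subunit (0.27 ± 0.048, adjusted p = 0.154), Ryk, a Wnt receptor (0.21 ± 0.0416, adjusted p = 0.267), Cyp27a1, a mitochondrial sterol hydroxylase of bile acid synthesis (0.38 ± 0.0748, adjusted p = 0.267), and Pam, which amidates peptide hormones (0.33 ± 0.0672, adjusted p = 0.32). Among falls, the next after the 3 called genes were Car2, a cytosolic carbonic anhydrase (-0.26 ± 0.0493, adjusted p = 0.267), and Kdm5b, a histone demethylase (-0.24 ± 0.0534, adjusted p = 0.51), which did not pass either. A further probe set moved the same way for Tmcc2 (0.22) and Rpl22 (0.14), and gave 0.053 for Ryk and -0.026 for Kdm5b. Pam passed only without wild type replicate 4 (adjusted p = 0.00835).

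Stk25, Neu2 and Stk11ip all lie on chromosome 1, as does Prkag3. In the gene order of assembly GRCm38.p6, Stk11ip is the measured gene 26 places after Prkag3, Neu2 74 places after it and Stk25 114 places after it, out of 708 measured genes on that chromosome. Cyp27a1 is the measured gene directly before Prkag3, and Pam, Tmcc2 and Kdm5b follow at 126, 198 and 219 places. Of the 28 placed probe sets at an unadjusted p below 0.001, 12 were on chromosome 1, which holds 5.95% of the placed probe sets (one-sided Fisher's exact test, odds ratio 12, p = 2.32e-08, computed after the positions of the called genes had been seen). The remaining 5 genes of these 12 were Gdap1 (0.34 ± 0.0781) and Clasp1 (0.40 ± 0.0971), both higher in knockout, Ramp1 (-0.33 ± 0.0813) and Atp1b1 (-0.46 ± 0.103), both lower, and Gpc1 (0.21 ± 0.0535), higher, and none passed the threshold. Of the list members named below, Cab39, Ndufs1, Fn1 and Des also lie within 20 Mb of Prkag3.

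**Figure D2:**
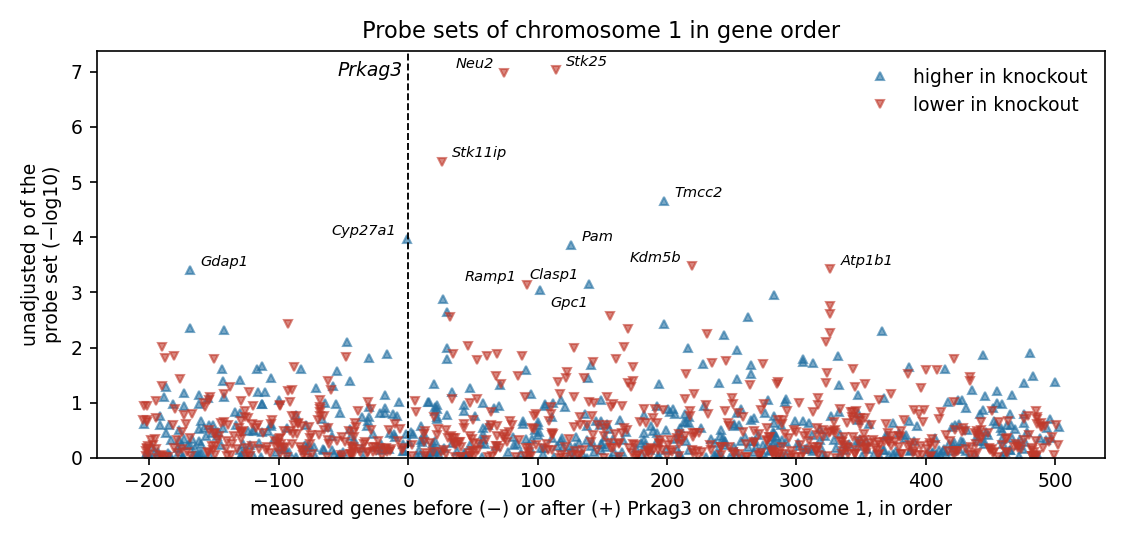
Unadjusted limma p as −log10 (vertical axis) of each probe set on chromosome 1 against the place of its gene before or after Prkag3 among the 708 measured genes in GRCm38.p6 order (horizontal axis, dashed line at Prkag3), with upward triangles for higher and downward triangles for lower in knockout. The labelled genes have p below 0.001, and Neu2 and Stk25 reach the highest values, 6.99 and 7.03.

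Across the array most differences were small. The median size of a log2 change was 0.044, against a median standard error of 0.0602, and 7 probe sets differed by over 0.5. At an unadjusted p below 0.05 there were 1366 probe sets, 757 higher and 609 lower, where 1131 would come by chance. The groups did not overlap in 86 probe sets, 0.38% of those tested, where chance gives 0.216%.

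Genes of mitochondrial oxidation, slow fibres and glycolysis lay lower in the knockout as groups, with small median changes. Of 46 measured respiratory chain genes 41 were lower, with a median change of -0.055, and of 18 genes of the tricarboxylic acid cycle 15 were lower, with a median of -0.079. In fatty acid uptake and oxidation 20 of 24 genes were lower (median -0.051), in the slow oxidative fibre list 11 of 13 (median -0.23) and in glycolysis 12 of 15 (median -0.056). These 5 of the 26 lists passed with camera at its preset correlation, with adjusted p = 8.96e-07, 0.000226, 0.00419, 0.0207 and 0.0463 in that order. No list passed with an estimated correlation, with adjusted p = 0.463 for the respiratory chain, the tricarboxylic acid cycle and glycolysis, and adjusted p = 0.675 for fatty acid oxidation and slow fibre. The estimates were 0.21 for the respiratory chain, 0.28 for the tricarboxylic acid cycle, 0.447 for fatty acid oxidation, 0.69 for slow fibre and 0.0857 for glycolysis. A preset of 0.01, below all of these, makes camera's p too small, so passing at the preset is weak evidence for a list.

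No member of these 5 lists passed over all probe sets, and 1, Mdh1, passed adjusted over the list alone. Mdh1, the cytosolic malate dehydrogenase, fell by 0.20 ± 0.0517 (list-adjusted p = 0.0214), while its 3 further probe sets gave -0.054, -0.053 and 0.0080. In the respiratory chain, 8 genes were lower and 0 higher at an unadjusted p below 0.05. Atp5g1, which encodes subunit c of ATP synthase, gave -0.15 ± 0.0448 and Ndufs1 of complex I -0.13 ± 0.0483, with list-adjusted p = 0.223 and 0.246. In fatty acid oxidation 5 genes were lower and 0 higher at that level. Hadhb of the mitochondrial trifunctional protein gave -0.16 ± 0.0563 and the fatty acid transporter Cd36 -0.18 ± 0.0714 (list-adjusted p = 0.193 for both), with -0.42 and -0.25 at the other Cd36 probe sets and -0.00052 at the other Hadhb probe set. The glycolytic enzymes Pgk1 (-0.12 ± 0.049) and Ldha (-0.095 ± 0.0477) had list-adjusted p = 0.358 and 0.464, and the other Pgk1 probe sets gave -0.050 and -0.055. Without genes within 20 Mb of Prkag3, an alternative added after seeing the data, the same 5 lists passed.

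The slow fibre genes varied widely within each genotype. The mean level of the list, each gene centred on its average, ran from -0.55 to 0.74 over the knockout arrays and from -0.51 to 0.73 over the wild type arrays, and the genotypes differed by -0.26 with SDs of 0.466 and 0.482 (n = 6, exact permutation test, two-sided p = 0.364). The same exact permutation test of the array level gave p = 0.0346 for the respiratory chain, 0.0606 for the tricarboxylic acid cycle, 0.297 for fatty acid oxidation and 0.0498 for glycolysis, and none of the 5 passed over the 26 lists (adjusted p = 0.394 or more). Casq2, the calsequestrin of slow and cardiac muscle, gave -0.12 ± 0.0625 and myoglobin, Mb, -0.14 ± 0.0874 (list-adjusted p = 0.404 for both), with 0.047 at a dimmer Mb probe set. Within wash runs 1, 2 and 3 the slow fibre difference was -0.19, 0.32 and -0.90. The respiratory chain difference was -0.076, -0.0090 and -0.082, that of the tricarboxylic acid cycle -0.13, 0.030 and -0.13, that of fatty acid oxidation -0.11, 0.039 and -0.11, and that of glycolysis 0.0029, -0.050 and -0.12. With the wash run as a block, camera was run at its preset correlation only. Its adjusted p was 2.09e-06, 0.000214, 0.0046 and 0.00771 for respiratory chain, tricarboxylic acid cycle, fatty acid oxidation and slow fibre. For glycolysis it was 0.0516, which no longer passed. With the slow fibre level as a covariate, added after seeing the data, the respiratory chain (camera, adjusted p = 0.000195) and the tricarboxylic acid cycle (adjusted p = 0.0213) passed and fatty acid oxidation did not (adjusted p = 0.257). These values also used the preset correlation. Without knockout replicate 2, the covariate left only 0.241 of the median change of these 3 lists, so they do not separate genotype from slow fibre share.

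**Figure D3:**
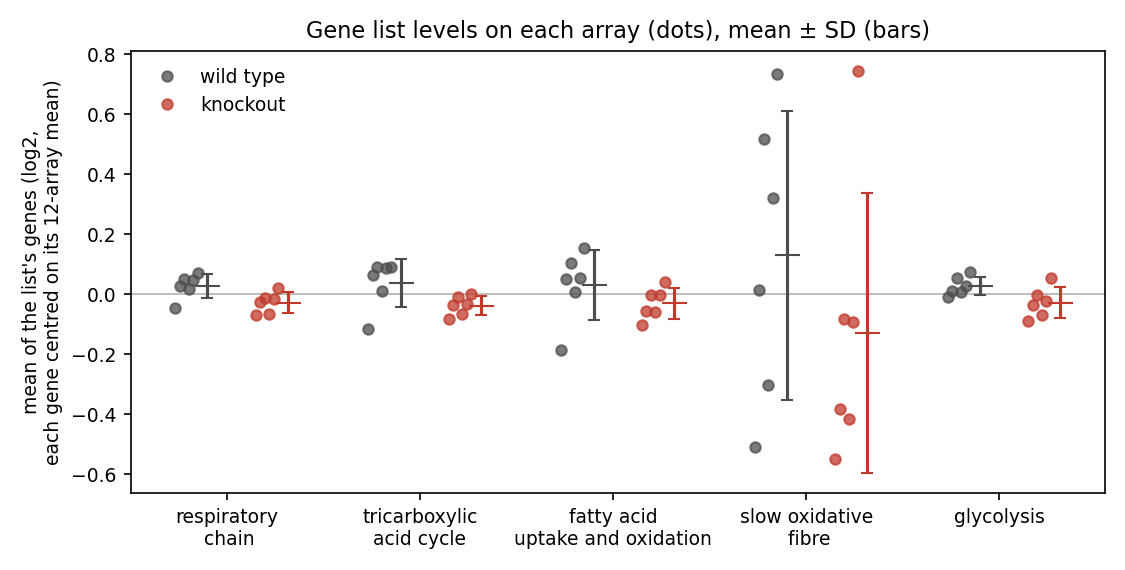
Mean level of the genes of 5 lists on each array (vertical axis, log2, each gene centred on its 12-array mean), with wild type in grey and knockout in red; dots are the 6 arrays per genotype and bars the mean ± SD. The slow oxidative fibre list spans -0.55 to 0.74 in knockout and overlaps between genotypes, while the shifts of the other 4 lists are under 0.1.

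Genes of lipid synthesis moved in both directions. In the list of fatty acid and triglyceride synthesis, 3 genes rose and 1 fell adjusted over the list alone, and none passed over all probe sets. Scd2, a stearoyl-CoA desaturase, rose by 0.28 ± 0.0678, the lipogenic transcription factor Srebf1 by 0.23 ± 0.071 and fatty acid synthase, Fasn, by 0.22 ± 0.0764, with list-adjusted p = 0.00971, 0.0237 and 0.0372. The other Scd2 probe sets gave 0.13 and 0.043. Lpin1, a phosphatidate phosphatase that also coactivates genes of fatty acid oxidation, fell by 0.25 ± 0.0734 (list-adjusted p = 0.0237), with -0.16 at its other probe set. As a whole the 15 genes, 9 higher and 6 lower, did not pass (camera, adjusted p = 0.152). Srebf1 gave -0.031, 0.33 and 0.39 and Fasn -0.0016, 0.27 and 0.40 in wash runs 1, 2 and 3. The mean of the list differed by -0.085, 0.14 and 0.11 in these runs, and that of the adipocyte markers moved alongside it, by -0.052, 0.17 and 0.14.

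In glycogen metabolism, Ugp2, which makes the UDP-glucose used for glycogen, fell by 0.25 ± 0.0616 and the branching enzyme Gbe1 by 0.35 ± 0.0958, with list-adjusted p = 0.0116 and 0.0148, and neither passed over all probe sets. All 5 Ugp2 probe sets were lower, from -0.28 to -0.14. Gbe1 was dim, below the median level, with a mean log2 intensity of 6.07 in knockout and 6.42 in wild type. In wash runs 1, 2 and 3, Gbe1 gave -0.17, -0.22 and -0.67 and Ugp2 -0.21, -0.14 and -0.41. The 16 genes of the list were 8 higher and 8 lower, with a median of 0.0027, a mean of -0.024 and an adjusted p of 0.658 with camera, whose direction was down. Ppargc1a, the coactivator of mitochondrial biogenesis, fell by 0.29 ± 0.0758 (list-adjusted p = 0.0284) and its 4 further probe sets gave -0.24 to -0.041. It did not pass over all probe sets (limma, adjusted p = 0.564). The other members of its list of mitochondrial and metabolic transcription factors did not pass adjusted over the list alone either. Of the 19 members 15 were higher (camera, adjusted p = 0.142).

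The remaining metabolic and signalling lists did not pass, and their members are given as values only. Of 7 AMPK subunits and upstream kinases 4 were lower (adjusted p = 0.951), with Cab39, a partner of LKB1, at -0.10 ± 0.0555 and -0.23 at a dimmer probe set, and Stk11, which encodes LKB1, at 0.086 ± 0.0527, against -0.065 at a dimmer Stk11 probe set. Glucose uptake and pyruvate dehydrogenase control (5 higher, 7 lower, adjusted p = 0.464) had Dlat at -0.16 and Pdha1 at -0.089, both subunits of pyruvate dehydrogenase, with -0.23 and -0.049 at the dimmer Dlat probe sets and -0.22 at the dimmer Pdha1 probe set. Insulin signalling (9 higher, 8 lower, adjusted p = 0.543) had the kinase Akt2 at 0.18 ± 0.0522 (list-adjusted p = 0.0605), against 0.022 at a dimmer probe set, and the adaptor Grb10 at 0.15, against -0.12 and 0.015 at dimmer ones. Fast glycolytic fibre genes (7 higher, 5 lower, adjusted p = 0.657) had the myosin Myh1 at -0.11, with -0.14 and -0.022 at dimmer probe sets, and the troponin Tnnt3 at 0.069. Fasting and atrophy genes (12 higher, 5 lower, adjusted p = 0.29) had Cebpb at 0.22 and Gabarapl1 at -0.13, with 0.28 and -0.10 at dimmer probe sets of these genes. Circadian clock genes (12 higher, 5 lower, adjusted p = 0.152) had Npas2 at 0.13, against -0.080 at a dimmer probe set, and Hlf at 0.11, with 0.036 at a dimmer one. Immediate early and heat shock genes (9 higher, 11 lower, adjusted p = 0.994) had Myc at 0.11 and Ier3 at -0.091, and their median was -0.022 where camera's direction was up. Interferon response genes (4 higher, 14 lower, adjusted p = 0.397) had Tap1 at -0.075 and Irf9 at -0.065.

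No list of markers for other cell types passed in the comparison of all probe sets. Pmp22, a myelin protein of Schwann cells, rose by 0.25 ± 0.0743 adjusted over its list alone (list-adjusted p = 0.0375), while the 9 nerve genes were 5 higher and 4 lower (adjusted p = 0.657). Satellite cell and regenerating fibre genes were higher in 7 of 9 (adjusted p = 0.138), with M-cadherin, Cdh15, at 0.14 ± 0.0531 and desmin, Des, at 0.11 ± 0.0489, against -0.10 at a dimmer Des probe set. The array level of this list differed by 0.045 (SDs 0.0277 and 0.0142, n = 6), with every knockout array above every wild type array, an exact permutation p = 0.0022 that is the smallest possible, and an adjusted p of 0.0563 over the 26 lists. Without Des, which lies near Prkag3, it differed by 0.037, the genotypes overlapped and the exact permutation p was 0.00433, computed after seeing the data. Neuromuscular junction genes (6 higher, 5 lower, adjusted p = 0.318) had the acetylcholine receptor subunit Chrne at 0.13 and Colq at -0.098. Adipocyte genes (6 higher, 3 lower, adjusted p = 0.2) had Cidec at 0.26 and Cidea at -0.13, and macrophage and leukocyte genes (11 higher, 5 lower, adjusted p = 0.405) had Cd74 at 0.18 and Cd68 at -0.13. Endothelial genes (3 higher, 8 lower, adjusted p = 0.142) had the VEGF receptor Kdr at -0.22 and Tie1 at -0.11, and 9 of them passed as a list, lower in knockout, when only probe sets above the median level were kept (adjusted p = 0.0421). Smooth muscle and pericyte genes (2 higher, 7 lower, adjusted p = 0.405) had Kcnj8 at -0.15 and Notch3 at -0.082. Fibroblast genes (4 higher, 9 lower, adjusted p = 0.951) had Pdgfra at 0.15 and fibronectin, Fn1, at 0.099, against -0.048 and -0.026 at dimmer probe sets of these genes, with a median of -0.022 where camera's direction was up, and tendon genes (1 higher, 7 lower, adjusted p = 0.405) had Scx at 0.072 and Cilp2 at -0.065. Keratinocyte genes (1 higher, 7 lower, adjusted p = 0.142) had Krt14 and Krt5 both at -0.21, with -0.15 and -0.037 at the dimmer Krt14 probe sets, and their list level was 0.86 on wild type replicate 1 against -0.14 to -0.021 on the other wild type arrays. Of the erythroid markers 4 were measured and the list was not tested.

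With fry, which asks whether a list moves at all, no list passed for a shift in 1 direction (adjusted p = 0.145 or more). For changes in either direction the respiratory chain (adjusted p = 0.0386), fatty acid and triglyceride synthesis (adjusted p = 0.0386) and the neuromuscular junction (adjusted p = 0.0238) passed. With camera at its preset correlation, which all the values below use, the count of 5 lists ranged from 2 to 6 when 1 array was left out. It was 2 without knockout replicate 6, and 3 without knockout replicate 4 or wild type replicate 4, 5 or 6. Respiratory chain and tricarboxylic acid cycle passed in all 12 of these fits. Fatty acid oxidation was lost without knockout replicate 6 or wild type replicate 4 or 5 (adjusted p up to 0.164), glycolysis without knockout replicate 2, 4 or 6 or wild type replicate 4, 5 or 6 (up to 0.191), and slow fibre without knockout replicate 1, 4, 5 or 6 or wild type replicate 4, 5 or 6 (up to 0.327). Fasting and atrophy genes, higher in knockout, passed without knockout replicate 3 (adjusted p = 0.0495) or wild type replicate 5 (adjusted p = 0.0135), and fatty acid and triglyceride synthesis, also higher, without wild type replicate 4 (adjusted p = 0.0453). Glycolysis was also lost with the replicate number as a block (adjusted p = 0.0706), after centring each array on its median (adjusted p = 0.0859) and with array weights (adjusted p = 0.179). The cage letter as a block, added after seeing the data, lost it too (adjusted p = 0.0556), and the other 4 lists passed in each of these. With the fluidics module as a block, added after seeing the data, the respiratory chain alone of the 26 lists passed (adjusted p = 0.00324).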

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

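In 14 of the 182 groups of 6 arrays examined, 9.1 of which chance would give, the highest or lowest array stood apart from the other 5 by Dixon's rule, and the gap as a share of the group's range is given below for each. These values carry no explanation.

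Wild type replicate 1 was high for the epidermal keratins Krt5 (0.822, log2 intensity 8.78 against at most 7.81) and Krt14 (0.664), for the keratinocyte list as a whole (0.877) and for the lipid droplet gene Cidea (0.688). Knockout replicate 5 was low for Krt5 (0.717) and high for the ribosomal protein probe sets (0.628, mean level 0.18 against at most 0.055). Knockout replicate 1 was low for Prkab1 (0.681), for Cyp27a1 (0.699, log2 intensity 9.95 against 10.2 to 10.3) and for the glycogen metabolism list (0.708). Knockout replicate 2 was high for the slow oxidative fibre list (0.64, list level 0.74 against at most -0.084) and low for the endothelial receptor Tie1 (0.715). Knockout replicate 3 was low for the nerve and Schwann cell list (0.644). Wild type replicate 2 was low for Mdh1 (0.709, log2 intensity 12.3 against at least 12.4), and wild type replicate 6 was high for Ldha (0.69).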

How the results depend on the processing

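Cage, fluidics module, single wash runs, lists without genes near Prkag3 and the slow fibre covariate were chosen after the data were seen. The count of 3 probe sets and 3 genes stayed at 2 or 3 in every fit of all arrays and in every fit without 1 array (2 to 3), and Stk25 and Neu2 were among the calls in each of these. Stk11ip was lost under the replicate block, median centring, further quantile normalization, the module block and 10 of the 12 fits without 1 array, and fell below the filter on dim probe sets. Rescaling moved the median of all probe sets by under 0.1.

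The 5 lists ranged from 2 to 6 without 1 array. They became 4 with median centring, array weights, the wash run block and the cage block, each without glycolysis, and 6 with the filter on dim probe sets, which added the endothelial list. They became 0 with an estimated correlation, 0 with fry, 1 with the module block and 2 with the slow fibre covariate, and the cause was not tested. With that covariate the slow fibre list itself did not pass (adjusted p = 0.956), because its mean is then held equal between the genotypes by construction.

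Wash runs alone have 2 arrays per genotype, which leaves fewer samples for each test. They gave 0, 0 and 12 probe sets, 0, 0 and 10 genes, and 9, 8 and 13 lists for runs 1, 2 and 3. The run 3 genes included Stk25 and also Atp2a2, Myh7, Myl2, Tnnc1, Tnni1, Tnnt1 and Tpm3, which are members of the slow fibre list. The level of that list differed by -0.90 in run 3, and whether slow fibre content gave these calls was not tested. In run 1 the sign turned for Prkab1 (-0.046), Cab39 (0.014), Srebf1 (-0.031), Fasn (-0.0016), Myh1 (0.016), Gabarapl1 (0.048) and Cilp2 (0.076), and for the mean of the glycolysis list (0.0029, adjusted p = 0.999). In run 2 it turned for Prkab1 (-0.037), Prkag2 (0.13), Ier3 (0.075), Cd68 (0.034) and Tie1 (0.0042), and for the lists of fatty acid oxidation (adjusted p = 0.308), tricarboxylic acid cycle (0.452) and slow fibre (1.21e-07). In run 3 it turned for Prkag1 (0.0011), Cd74 (-0.049), Scx (-0.00042), Notch3 (0.068) and Krt14 (0.019).

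The AMPK subunits, near 0 throughout, also changed sign elsewhere, and the cause was not tested. Prkab1 gave -0.010 with array weights, -0.049 as the mean of its probe sets and -0.017 to 0.047 without 1 array. Prkag1 gave -0.056 to 0.010 without 1 array, 0.0079 without wild type replicate 1. Prkag2 gave 0.020 with the module block and -0.046 to 0.029 without 1 array. No other named gene changed sign in a fit without 1 array.

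The labels do not state that the replicate numbers of the titles pair the arrays. Same-numbered arrays share a cage letter in 6 of 6 pairs, and each pair also shares a scan day. Their deviations correlated at -0.15 to 0.203, over 0.1 in 2 pairs, and 1 of 12 arrays correlated best with its own number. Such weak correlations do not exclude that the numbers mark pairs. With the replicate block there were 2 probe sets, 2 genes and 4 lists, without Stk11ip (adjusted p = 0.115) and glycolysis (adjusted p = 0.0706). Prkag3 was not analysed here, so its alternatives were not run. Signal over background is not recorded in the values used, so dim probe sets may be understated. Only 44.8% of simulated changes of 0.25 were recovered, and with fewer changed probe sets than the 200 simulated the share would be lower.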

Other observations

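The ribosomal protein group, the nearest neighbour and probe sequence tests, the tests over all of chromosome 1 and the splits within wash runs were chosen after the results they concern were seen.

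Ribosomal protein genes lay higher in the knockout muscle. Of 202 probe sets that name a ribosomal protein gene, 180 were higher and 22 lower, with a median change of 0.10, and none passed over all probe sets. At an unadjusted p below 0.05, 76 of the 202 were higher and 1 lower. The 100 probe sets that name 1 gene alone were higher in 85 and lower in 15 (median 0.085). The array mean of all 202 differed by 0.0999 (SDs 0.0685 in knockout and 0.0413 in wild type, n = 6, exact permutation p = 0.00649). Knockout replicate 5 stood apart at 0.18, against -0.018 to 0.055 on the other knockout arrays, and without it the difference was 0.074 (exact permutation p = 0.013). This array also had the highest 3' to 5' ratio, 0.0017 against -0.22 to -0.074 in the other knockout arrays. For the 202, camera gave p = 7.59e-35 with the preset and p = 0.0122 with an estimated correlation. Within wash runs 1, 2 and 3 the difference was 0.048, 0.12 and 0.13. Without 1 array the median ran from 0.072 to 0.12, and it was 0.11 with arrays centred on their median and 0.080 after a further quantile normalization. A shift of bright probe sets by the normalization is argued against, since probe sets of the same level moved by 0.0065, a ratio of 0.0643 to the ribosomal shift. Among 100 splits of the 12 arrays, 2, the real one included, gave a median this large, with 0.105 as the highest other, but the group was picked because it stood out, so neither this count nor the p-values above exclude chance. Loss of the subunit and differences in RNA quality, between litters or in the sampled tissue stay open, and none of them was tested for this group.

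All 3 called genes lie within 20 Mb of Prkag3 in GRCm38.p6, a stretch holding 201 of 12377 placed genes (one-sided Fisher's exact p = 4.22e-06), as a segment of the targeted stem cell's chromosome carried along with the knockout allele would give. The same stretch held 11 of 333 probe sets at an unadjusted p below 0.01 against 224 of 20026 elsewhere (Fisher's exact test, odds ratio 3.02, p = 0.00177), or 3.3% against 1.12%, and without the called genes the odds ratio was 2.2 (p = 0.036). By that share the stretch does not stand alone, since windows of 40 Mb reached 5.37% on chromosome 1, 4.79% where they lay apart from the stretch, and 3.61% on chromosome 8, the highest on other chromosomes. An effect on the nearest genes alone is argued against, because 2 called genes lay over 1 Mb away in every fit without 1 array, and chromosome 1 beyond 20 Mb also held 6 probe sets below 0.001 (Fisher's exact test, odds ratio 8.23, p = 0.000285). Sequence differences under the probes and true differences in level cannot be told apart, as 0 of the 3 genes have a further probe set, and the labels give generation F7 but no stem cell strain, so a passenger segment stays a hypothesis and an effect of the lost subunit on these genes stays open.

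The count of 3 probe sets was reached by 3 of 100 splits drawn from the 462 possible, the real one included, which is under the 0.05 set beforehand. This argues against chance for the count but, as a sample of the splits, does not exclude it. The highest other count was 8, above the real one, and what gave it was not tested. That split put all 4 arrays of wash run 2 on 1 side and none of run 3, and its sides also differed by -0.45 in slow fibre level. Foxo1, Ppp1r3c and Sesn1 were among its genes. Its sides also differed in the level of the fasting and atrophy list, to which Sesn1 belongs. That level ran from -0.29 to 0.028 on the side with wash run 2 and from 0.014 to 0.32 on the other. The other split that reached 3 held 2, 3 and 1 arrays of the wash runs and differed by -0.32 in slow fibre level. Its genes included Klf15, also of the fasting and atrophy list. The level of that list ran from -0.29 to 0.062 on the side with knockout replicates 1 and 3, and from 0.014 to 0.32 on the other. None of the genes of these splits is in the slow fibre list. Among 100 of the 108 splits that part each wash run evenly, as the real one does, 1, the real one, reached 3 probe sets, the highest other count was 1, and the fit with the wash run as a block gave 3.

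The lower oxidative lists are less firmly tied to genotype. Their 88 genes had a median change of -0.057, and with the slow fibre level as a covariate it kept 0.808 of its size, but 0.241 without knockout replicate 2, so a different share of slow fibres in the muscle piece cannot be told apart from genotype. A difference in RNA quality stays open, because the 3' to 5' ratio differed by only 0.0127 between the genotypes (exact permutation p = 0.747) and as a covariate, which kept 1.05 of the median, it had little to move. For the count of 5 lists, 58 of 100 splits gave as many, the real one included, with 12 as the highest other, and 50 of 100 splits that part each wash run evenly did, with 14 as the highest other, so chance could give it.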
